A study of Mus musculus with 12 samples.

How the data were processed

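The series measured total RNA of the mouse olfactory bulb on 12 expression arrays, 3 for each combination of genotype (wildtype or hGFAP transgenic, on the FVB/N strain) and age (P23, which is 23 days after birth, or 4 months). The label hGFAP was read as human GFAP, glial fibrillary acidic protein. Per the titles, every array has its own number, and no number is shared between groups. The titles do not say whether the number stands for an animal. Each array was treated as an independent sample, and no pairing was used. Sex, litter and hybridization date are not given in the labels.

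The deposited table holds the intensity of each probe set on each array as a linear signal, 1 value for each of 12488 probe sets. Probe set names and the annotation are those of the Affymetrix MG-U74Av2 array, and the software that summarised, background corrected and called the signals is not given in the sources used here. The authors scaled each array as a whole: the mean of the deposited values left after dropping the lowest and highest 2 percent is equal on the 12 arrays. The medians of the arrays were not equal, with a ratio of 1.114 between the highest and the lowest, above the limit of 1.1 set in advance, and each array was therefore rescaled to the median of the array medians. Values below 209.142, the 20th percentile of the scaled table, were raised to that floor, and all values were taken to log2. After leaving out 66 control probe sets, the 7453 probe sets with a mean log2 value above the 40th percentile (9.43, a signal of 689) were kept for tests. Signals below refer to scaled values on the linear scale. Where all arrays of a group lay at the floor, the fold change is a lower bound and is given as such. For arrays, their number limits the precision: there are 3 per group.

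Of the 12422 probe sets that are not controls, 10833 carried 1 gene symbol. Each gene was represented by its probe set with the highest mean over all arrays, which left 5664 genes. Gene coordinates are from the RefSeq annotation of GRCm38.p6.

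Tests were made in limma 3.58.1 under R 4.3.3, with 1 mean for each of the 4 groups, 8 residual degrees of freedom and empirical Bayes moderation with a trend on the mean signal (6.27 prior degrees of freedom). All tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the kept probe sets, with a threshold of 0.05. The comparisons were transgenic against wildtype at P23, the same at 4 months, the difference between those effects (the interaction), and 4 months against P23 in wildtype. Errors of log2 changes are standard errors (SE) from that model, and errors of group means are standard deviations (SD) over 3 arrays. The p-values may measure only the spread between these samples, since nothing in the labels separates animals by cage, litter or day. Calls shared by both ages were tested by Fisher's exact test. The figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

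Gene lists, named genes, tests and most alternatives were chosen before the data were examined. The 33 lists held 805 genes, of which 632 were found on the array under 1 symbol and 488 were kept. Pathway lists were antioxidant and detoxification genes, heat shock proteins and chaperones, metal and iron handling, ER stress, Trp53 targets and cell death, proteasome, lysosome, reactive astrocyte genes, intermediate filaments, complement and antigen presentation, interferon response, cytokines and chemokines, growth factors, immediate early genes, synaptic genes, neuronal ion channels, proliferation, cholesterol synthesis and oxidative phosphorylation. Cell marker lists were astrocytes, microglia and macrophages, lymphocytes and granulocytes, oligodendrocytes and myelin, oligodendrocyte precursors, inhibitory interneurons, mitral and tufted cells, migrating neuroblasts, olfactory sensory neurons, olfactory ensheathing glia, endothelial and mural cells, meningeal cells and fibroblasts, red blood cells, and ependyma and choroid plexus. The 29 lists with at least 5 kept genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the 29 lists, and again with an estimated correlation and with fry. Beside the count over all kept probe sets, members were counted with p-values adjusted over the list alone.

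Genes were named by a fixed rule: 28 genes chosen in advance, the 12 genes with the largest change in each direction at each age among called genes whose groups do not overlap, up to 4 called members of each list (or 2 members of a list without calls), and the 10 largest in each direction for the interaction and the age comparison. Vim, Hspb1 and Cd44 among the fixed genes fell below the filter, and Slc1a3, C4b and Slc17a7 had no probe set with 1 symbol. Another of the fixed genes is not reported.

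The alternatives were scaling to the 75th percentile or by quantiles, no floor or a floor at the 40th percentile, no filter or a filter at the 60th percentile, moderation without a trend, array weights, a fit of only the groups compared, the mean of all probe sets of a gene, an estimated correlation, and leaving out each array in turn. Added after the data were seen were the values as deposited and scaling to the bacterial hybridization controls, which are spiked into the labelled sample and do not come from the tissue. Sets of genes sharing a protein family were also added then. The procedure was tested on simulated data made from these arrays, with changes planted in known probe sets: planted 2-fold changes were recovered at 75.4 percent at P23, 71.2 percent at 4 months, 65.2 percent for the interaction and 72.3 percent for age, and planted 1.5-fold changes at 43.9, 40.9, 15.4 and 44.6 percent. Of the calls made there, 2.8, 8.2, 5.2 and 6.9 percent were false, in the same order. The simulation drew independent noise for each probe set and changed few of them. Its 4-month comparison called 147 probe sets, against 2134 in the real one, so these rates need not hold for the real arrays.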

Results

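Expression was measured in the olfactory bulb of wildtype and hGFAP transgenic FVB/N mice at P23 and at 4 months, with 3 arrays in each of the 4 groups. Going by its title, the series asks how expression in the bulb of mice carrying a GFAP transgene differs from wildtype, and the 2 ages allow the difference to be followed in time. Pearson correlations across probe sets lay between 0.951 and 0.972 for the 12 pairs of arrays within a group and between 0.893 and 0.966 for the 54 pairs between groups; genes are not independent replicates. The ratio of the 3' to the 5' beta-actin control probe sets, a measure of RNA integrity, was 1.24 ± 0.04 (SD, n = 3) in wildtype and 1.31 ± 0.13 in transgenic bulb at P23, and 1.34 ± 0.06 and 1.21 ± 0.07 at 4 months. The same ratio for Gapdh ran the other way between genotypes, at 0.884 ± 0.055 and 0.807 ± 0.014 at P23 and 0.8002 ± 0.0186 and 0.835 ± 0.016 at 4 months. The share of values at the floor was 19.9 and 19.8 percent at P23 and 20.6 and 19.5 percent at 4 months.

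**Figure D1:**
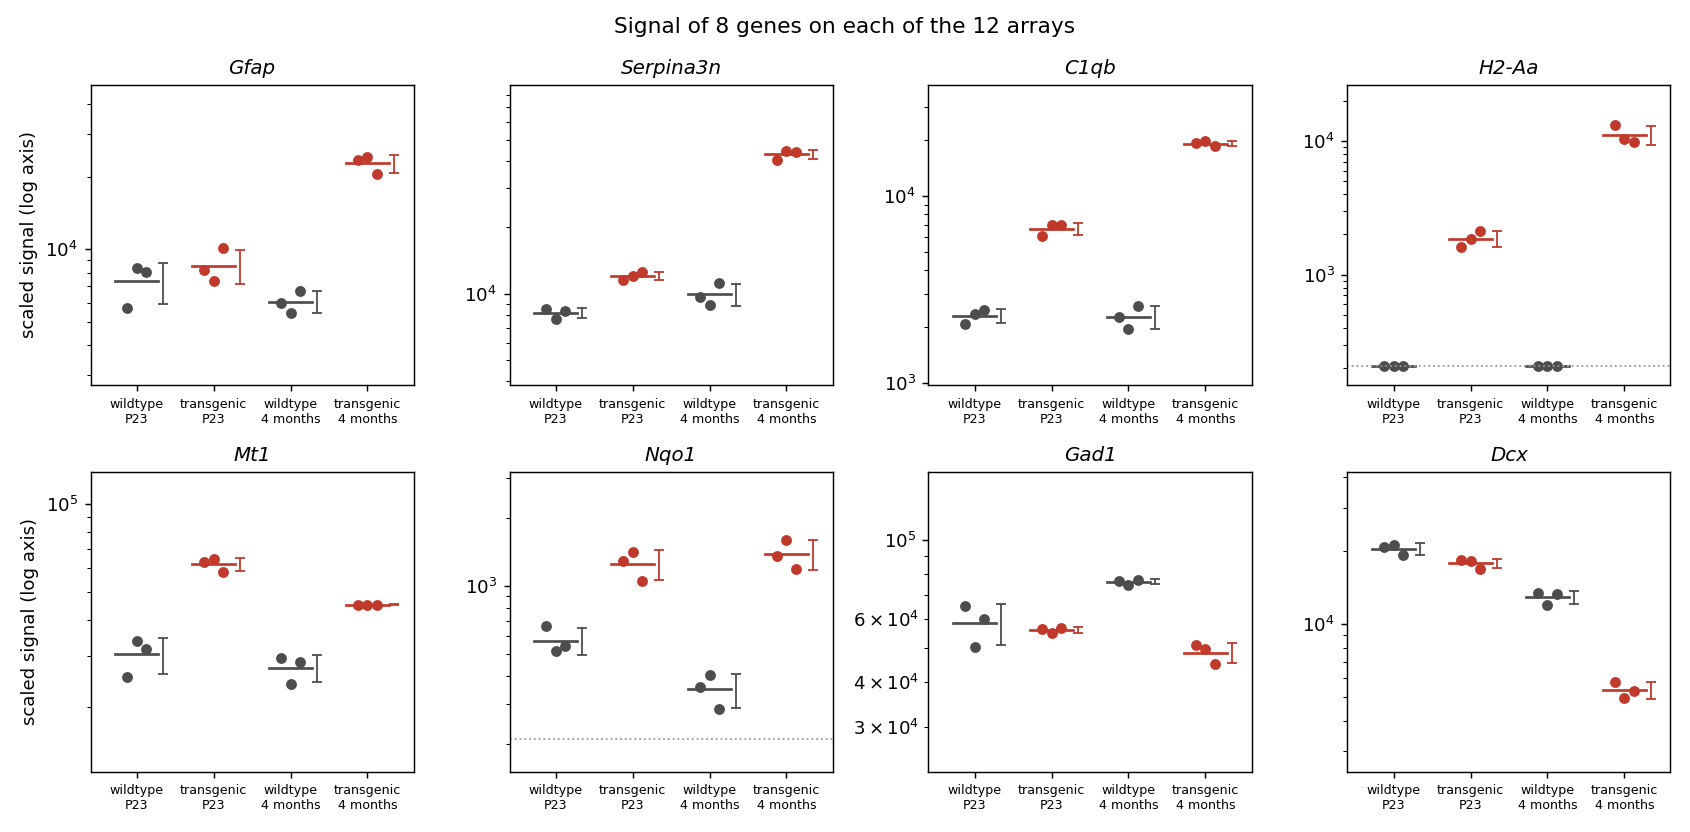
Scaled signal (linear values on a log axis) of 8 genes in the 4 groups, with 1 point per array, the mean as a line, the SD as a bar and the floor of 209.142 as a dotted line. Serpina3n rose from 8214 to 12060 at P23 and from 9923 to 42790 at 4 months, while Gad1 and Dcx were lower in transgenic bulb at 4 months.

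At P23 the transgenic bulb had higher levels of genes of inflammation, of reactive astrocytes and of oxidative stress defence, all with n = 3 arrays per group. H2-Aa (Entrez 14960, chromosome 17, 34282744 to 34287823), a chain of the class II antigen-presenting complex, reached 1863 ± 255 (SD), at least 8.85-fold above wildtype, where all 3 arrays lay at the floor. The chemokines Ccl2 and Cxcl1 were at least 11.3-fold and at least 8.54-fold higher on the same terms. Ephx1, an epoxide hydrolase of detoxification, was 10-fold higher (log2 change 3.32 ± 0.30, SE), and Anxa3 was 8.08-fold higher (3.01 ± 0.20). Cp, the copper-binding ferroxidase ceruloplasmin, was 7.06-fold higher (2.82 ± 0.27) and the retinaldehyde dehydrogenase Aldh1a1 4.08-fold higher (2.03 ± 0.10).

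Microglia and macrophage markers formed the list with the lowest p: 13 of 18 rose at P23, 0 fell and 15 rose when adjusted over the list alone (limma, 0 lower at an unadjusted p under 0.05), with a median log2 change of 1.05 (camera adjusted p = 1.97e-29). Ctss, a lysosomal cathepsin of these cells, rose from 7795 ± 600 to 20420 ± 757 (1.39 ± 0.08, adjusted p = 2.36e-07), and Lyz2, lysozyme, by 2.32 ± 0.28 (0.00022). C1qb (Entrez 12260, chromosome 4, 136880126 to 136886200), a subunit of complement C1q, rose from 2279 ± 198 to 6674 ± 521 (1.55 ± 0.12, adjusted p = 1.73e-06), while its other probe set did not pass (-0.32, adjusted p = 0.475). Of 20 complement and antigen presentation genes, 11 rose (15 adjusted over the list alone; camera adjusted p = 3.59e-27). Of 12 interferon response genes, 2 rose (8 adjusted over the list alone; camera adjusted p = 8.41e-11), with Ifitm3 at 1.39 ± 0.11. Of 21 lysosome genes 4 rose (9 higher and 1 lower adjusted over the list alone; camera adjusted p = 4.62e-07), with Ctsz at 0.93 ± 0.15. Of 8 cytokines and chemokines 2 rose (3 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00121), a call that ended without a floor (0.0776).

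Of 20 reactive astrocyte genes, which astrocytes induce after injury, 8 rose at P23 (11 adjusted over the list alone; median 0.54, camera adjusted p = 2.14e-16). Osmr, the oncostatin M receptor, rose 3.47-fold (1.79 ± 0.17, adjusted p = 1.96e-05), and Nes, the intermediate filament protein nestin, 2.18-fold (1.12 ± 0.13, 0.000104). Serpina3n (Entrez 20716, chromosome 12, 104406646 to 104414334), a serine protease inhibitor, rose 1.47-fold (0.55 ± 0.09, adjusted p = 0.00304); with bacterial control scaling the change was 0.35 (0.0766). Gfap itself (Entrez 14580, chromosome 11, 102887336 to 102897200) stood at 7347 ± 1450 in wildtype and 8552 ± 1370 in transgenic bulb and did not pass (0.23 ± 0.15, adjusted p = 0.568). Its second probe set did not pass either (0.51 ± 0.19, 0.223). Whether these probe sets detect human transcripts is unknown.

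Antioxidant and detoxification genes rose in 8 of 26 cases (14 higher and 1 lower adjusted over the list alone; camera adjusted p = 5.05e-12). Txnrd1, thioredoxin reductase, rose by 0.80 ± 0.11 (adjusted p = 0.000485) and the glutathione peroxidase Gpx3 by 0.88 ± 0.15 (0.00573). Nqo1 (Entrez 18104, chromosome 8, 107388225 to 107403205), a quinone reductase, rose by 1.13 ± 0.24 (0.0228); its call ended without wildtype P23 replicate 11 (0.0783) or 12 (0.074), transgenic P23 replicate 5 (0.118) or 6 (0.105), or with only the P23 groups fitted (0.0654). Metal and iron handling genes rose in 5 of 12 cases (7 adjusted over the list alone; camera adjusted p = 4.78e-09). Among them the metallothioneins Mt1 (Entrez 17748, chromosome 8, 94178883 to 94180327) and Mt2 rose by 1.04 ± 0.10 and 0.92 ± 0.13, Mt1 from 30390 ± 4350 to 62080 ± 3110. Hmox1, heme oxygenase, did not pass (0.40 ± 0.11, 0.085). Of 16 heat shock proteins and chaperones 2 rose, with a median of -0.04 and a camera direction upward that did not pass (0.831): the small heat shock protein Hspb8 by 1.33 ± 0.15 and Cryab by 0.83 ± 0.16 (0.0119). The Cryab call ended without wildtype P23 replicate 12 (0.0586) or transgenic P23 replicate 5 (0.0656) or 7 (0.061).

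Markers of neurons and of resting glia mostly did not pass at P23. Ntsr2, a neurotensin receptor of astrocytes, fell from 13030 ± 1210 to 6972 ± 637 (-0.90 ± 0.12, adjusted p = 0.000433), and Dio2, the thyroid hormone deiodinase of astrocytes, changed by -0.94 ± 0.15 (0.00249). Of 19 astrocyte markers 2 fell (1 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.0891). Islr, a meningeal and fibroblast marker, fell by 0.55 on the log2 scale (0.00136). Of 27 synaptic genes 0 passed in limma, with 1 higher and 6 lower at an unadjusted p under 0.05 (camera adjusted p = 0.162). Of 21 inhibitory interneuron markers 1 fell (3 adjusted over the list alone; camera adjusted p = 0.126). Gad1 (Entrez 14415, chromosome 2, 70561303 to 70602014), the enzyme that makes GABA, was 58510 ± 7620 in wildtype and 55980 ± 919 in transgenic bulb (-0.06 ± 0.08, 0.857). The other markers Mbp (-0.27 ± 0.08, 0.13), Th (-0.26 ± 0.11, 0.309), Syt1 (0.12 ± 0.16, 0.833) and Fabp7 (0.17 ± 0.09, 0.479) did not pass.

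Oxidative phosphorylation genes were shifted downward as a group at P23 (1 of 46 fell; median -0.15, camera adjusted p = 4.12e-06), with adjusted p = 0.196 with an estimated correlation. The same held for cholesterol synthesis (median -0.28, camera adjusted p = 0.028; adjusted p = 0.26 with an estimated correlation) and mitral and tufted cell markers (-0.15, 0.0488; adjusted p = 0.255 with an estimated correlation), each with 0 members called by limma and 3 lower adjusted over the list alone; the unadjusted p was under 0.05 for 5 and 3 members. Immediate early genes (1 of 15 higher; median 0.36, camera adjusted p = 0.0168; adjusted p = 0.278 with an estimated correlation) and proliferation genes (0 of 14 called by limma, 1 higher at an unadjusted p under 0.05; median 0.17, -0.03 with bacterial control scaling; camera adjusted p = 0.021; adjusted p = 0.0724 with an estimated correlation) were shifted upward. Single arrays also ended calls of these lists. The cholesterol synthesis call ended without wildtype P23 replicate 4 (0.15), transgenic P23 replicate 5 (0.0804) or 7 (0.086), or wildtype 4 months replicate 3 (0.063). The immediate early call ended without wildtype P23 replicate 12 (0.0848), and the proliferation call without that array (0.0955) or transgenic P23 replicate 7 (0.0522). The mitral and tufted call ended without wildtype P23 replicate 11 (0.0832) or 12 (0.0848), transgenic P23 replicate 7 (0.241), wildtype 4 months replicate 3 (0.0604), 9 (0.0549) or 10 (0.0596), or transgenic 4 months replicate 2 (0.0534).

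The other lists were not called by camera at P23. Higher and lower members, with the camera adjusted p, were 0 and 0 of 17 for ER stress (0.977; 0 members at an unadjusted p under 0.05), 1 and 0 of 14 for Trp53 targets (0.0975), 0 and 0 of 24 for the proteasome (0.126; 4 lower at an unadjusted p under 0.05), 1 and 0 of 8 for intermediate filaments (0.385) and 2 and 0 of 17 for growth factors (0.0796). They were 0 and 0 of 17 for neuronal ion channels (0.863; 1 higher at an unadjusted p under 0.05), 1 and 0 of 7 for lymphocytes and granulocytes (0.174), 2 and 1 of 15 for oligodendrocytes and myelin (0.137), and 0 and 0 of 23 for neuroblasts (0.13; 2 higher and 4 lower at an unadjusted p under 0.05). For ensheathing glia they were 0 and 1 of 9 (0.162), for endothelial and mural cells 0 and 1 of 12 (0.13) and for meningeal cells 0 and 2 of 19 (0.25). Lists too short for camera were ependyma with 1 of 3 higher, and oligodendrocyte precursors, olfactory sensory neurons and red blood cells with 0 of 3, 0 of 4 and 0 of 4 called by limma (1, 0 and 3 lower at an unadjusted p under 0.05).

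In all, 122 probe sets were higher and 35 lower in transgenic bulb at P23 (limma; 989 at an unadjusted p under 0.05), and 53 and 1 of them changed more than 2-fold. The count of lower probe sets depended on the scaling and on single arrays. It was 15 by quantiles, 20 with values as deposited and 482 with bacterial control scaling (90 higher), which moved the median of all genes by -0.20. It was 12 without transgenic P23 replicate 5, 18 without 6 and 20 without 7, 13 without wildtype P23 replicate 11 and 19 without 12, and 22 without wildtype 4 months replicate 10.

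At 4 months genes of inflammation and of reactive astrocytes stood far above wildtype and neuronal genes were lower, with n = 3 arrays per group. H2-Aa reached 11060 ± 1790 (SD), at least 52.4-fold above wildtype, and Ccl2 6125 ± 1740, at least 28.5-fold, where all 3 wildtype arrays lay at the floor. Postn (Entrez 50706, chromosome 3, 54359267 to 54391041), the matrix protein periostin, rose 18.2-fold from 694.8 ± 110 to 12640 ± 1930 (log2 change 4.19 ± 0.18, SE). Mmp12, the metalloelastase of macrophages, rose 15.7-fold (3.97 ± 0.24). Gfap rose 3.76-fold from 6045 ± 631 to 22710 ± 1890 (1.91 ± 0.15, adjusted p = 3.5e-07), and its second probe set 2.89-fold (1.53 ± 0.19, 3.33e-05). Dcx (Entrez 13193, chromosome X, 143855842 to 143933396), the microtubule protein doublecortin of migrating neuroblasts, fell from 12860 ± 760 to 5338 ± 410 (-1.27 ± 0.08, adjusted p = 7.24e-08).

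Of 20 complement and antigen presentation genes 19 rose at 4 months (19 adjusted over the list alone; median 2.49, camera adjusted p = 7.78e-31). Cd74, the class II invariant chain, rose 12.5-fold (3.65 ± 0.18, adjusted p = 2.56e-09), and C1qb from 2261 ± 317 to 19110 ± 632 (3.09 ± 0.12, 1.36e-10). Of 18 microglia and macrophage markers 17 rose (18 adjusted over the list alone; median 2.32, camera adjusted p = 3.22e-29). Lyz2 rose 22.3-fold (4.48 ± 0.28, 4.03e-08), Tyrobp, a microglial signalling adaptor, 10.1-fold (3.34 ± 0.18), Cd68, a lysosomal marker of phagocytes, 5.65-fold (2.50 ± 0.13), and Ctss from 8057 ± 499 to 62690 ± 3260 (2.96 ± 0.08). Lysosome genes rose in 17 of 21 cases and 1 fell (camera adjusted p = 1.33e-20), with Ctsh at 2.79 ± 0.36 and Ctsz at 2.22 ± 0.15. Of 12 interferon response genes 11 rose (camera adjusted p = 1.84e-13), among them Ifitm3 (2.77 ± 0.11) and Gbp3 (2.14 ± 0.23). Of 8 cytokines and chemokines 3 rose and 2 fell, and the list was not called (0.129); the growth factor of macrophages Csf1 was 2.91-fold higher (1.54 ± 0.17). Adjusted over the list alone, 17 lysosome genes rose and 1 fell, 11 interferon genes rose, and 3 cytokines rose and 3 fell.

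Of 20 reactive astrocyte genes 18 rose (18 adjusted over the list alone; median 2.01, camera adjusted p = 9.41e-23). Cp rose 14.7-fold (3.88 ± 0.27), Osmr 12.5-fold (3.65 ± 0.17), Anxa3 10.5-fold (3.40 ± 0.20), Nes 4.63-fold (2.21 ± 0.13), and Serpina3n from 9923 ± 1170 to 42790 ± 2150 (2.11 ± 0.09). Astrocyte markers went both ways, with 3 higher and 8 lower of 19 (3 and 9 adjusted over the list alone; median -0.22, 0.05 with bacterial control scaling; camera adjusted p = 0.177). Ntsr2 fell from 13940 ± 644 to 4626 ± 762 (-1.60 ± 0.12, adjusted p = 2.16e-07), Gjb6, a gap junction protein of astrocytes, changed by -1.07 ± 0.13 (3.62e-05), and Slc1a2, the glutamate transporter, by -1.50 ± 0.36 (0.00603). Fabp7, a fatty acid binding protein of immature and radial glia, rose by 0.36 ± 0.09 (0.00992). Aqp4, the water channel of astrocyte endfeet, rose by 0.34 ± 0.09 (0.0129), and by 0.28 (0.0578) without transgenic 4 months replicate 1. Gja1 (-0.05, 0.807) and Glul (-0.22, 0.115) did not pass, although another probe set of Gja1 was lower (-0.93, 0.0379).

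Antioxidant and detoxification genes rose in 10 of 26 cases and fell in 2 (12 and 3 adjusted over the list alone; camera adjusted p = 7.29e-07). Ephx1 rose 6.15-fold (2.62 ± 0.30), Nqo1 3.98-fold (1.99 ± 0.24), Gpx3 2.83-fold (SE 0.15 on the log2 scale) and Txnrd1 2.35-fold (1.23 ± 0.11). Metal and iron handling genes rose in 7 of 12 cases and 1 fell (the same counts adjusted over the list alone; camera adjusted p = 7.61e-06), with Hmox1 at 0.84 ± 0.11, Mt1 at 0.72 ± 0.10 and Mt2 at 0.63 ± 0.13. Of 16 heat shock proteins and chaperones 2 rose, Cryab (1.28 ± 0.16) and Hspb8 (1.27 ± 0.15), and 7 fell (3 and 8 adjusted over the list alone; camera adjusted p = 0.389); with bacterial control scaling 3 rose and 0 fell. Hspa1b did not pass (-0.47, 0.0747).

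Meningeal and fibroblast markers rose in 8 of 19 cases (8 higher and 1 lower adjusted over the list alone; camera adjusted p = 4.56e-05), among them the collagen Col3a1 (1.75 ± 0.36) and the proteoglycan Lum (1.51 ± 0.22). Growth factors and trophic genes rose in 6 of 17 cases (6 adjusted over the list alone; camera adjusted p = 6.47e-05), with Igfbp3, an insulin-like growth factor binding protein, at 2.41 ± 0.24. Of 15 oligodendrocyte and myelin markers 7 rose and 3 fell (camera adjusted p = 0.000777; adjusted p = 0.0668 with an estimated correlation). Apod (1.40 ± 0.13), Gsn (0.99 ± 0.09) and Cldn11 (0.99 ± 0.16) were higher, while Mbp, myelin basic protein, was lower (-0.30 ± 0.08, 0.0153). The Mbp call ended without transgenic 4 months replicate 8 (-0.23, 0.0711) and with bacterial control scaling (-0.03, 0.905). Trp53 targets rose in 3 of 14 cases (camera adjusted p = 0.0223; adjusted p = 0.0616 with an estimated correlation), with the DNA damage gene Gadd45a at 1.28 ± 0.19. Of 7 lymphocyte and granulocyte markers 3 rose (camera adjusted p = 0.023; adjusted p = 0.169 with an estimated correlation), among them the immunoglobulin heavy chain Ighm (0.80 ± 0.15); the list's call ended without wildtype 4 months replicate 10 (0.0679) and with bacterial control scaling (0.0749). Adjusted over the list alone these counts were 7 and 3 for oligodendrocytes, 3 and 0 for Trp53 targets and 3 and 0 for lymphocytes and granulocytes.

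Neuronal lists were lower at 4 months, with medians that stayed negative under each scaling tried. Over all these lists 66 genes were called lower, and 35 of them stayed so with bacterial control scaling. Of 27 synaptic genes 22 fell (24 adjusted over the list alone; median -0.71, camera adjusted p = 2.2e-09), and 12 with bacterial control scaling (median -0.44). Nrgn, neurogranin, fell by 1.86 on the log2 scale (SE 0.38), and the synaptic vesicle calcium sensor Syt1 changed by -0.78 ± 0.16 (0.00246). Of 21 inhibitory interneuron markers 16 fell (18 adjusted over the list alone; median -0.66, camera adjusted p = 8.96e-07), and 10 with bacterial control scaling (median -0.39). Gad1 fell from 76320 ± 1270 to 48440 ± 3020 (-0.66 ± 0.08, 5.09e-05), Penk, proenkephalin, changed by -0.84 ± 0.09 and Th, the dopamine synthesis enzyme of periglomerular cells, by -0.55 ± 0.11 (0.00219). With bacterial control scaling the Th change was -0.28 (0.161). Of 17 neuronal ion channel genes 11 fell (1 higher and 11 lower adjusted over the list alone; median -0.64, camera adjusted p = 0.00066), among them the potassium channel subunit Kcnab2 (-1.04 ± 0.10). Mitral and tufted cell markers fell in 6 of 11 cases (10 adjusted over the list alone; median -0.57, camera adjusted p = 0.00177; adjusted p = 0.0664 with an estimated correlation), with the neurofilament Nefm at -1.51 ± 0.30. Of 23 neuroblast and immature neuron markers 14 fell and 1 rose (15 and 1 adjusted over the list alone; median -0.45, camera adjusted p = 2.03e-05), with the transcription factor Dlx2 at -0.99 ± 0.13. Oxidative phosphorylation genes fell in 25 of 46 cases (28 adjusted over the list alone; median -0.30, camera adjusted p = 2.03e-05; adjusted p = 0.167 with an estimated correlation), but in 0 with bacterial control scaling (median -0.03).

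Immediate early genes went both ways at 4 months, with 2 higher and 4 lower of 15 (2 and 5 adjusted over the list alone; camera adjusted p = 0.44): Nr4a1 fell 4.28-fold (-2.10 ± 0.28) and Egr1 2.71-fold (-1.44 ± 0.20), while Ier3 rose 2.7-fold (1.43 ± 0.14). Of 8 intermediate filament genes 3 rose and 3 fell (0.278), of 17 ER stress genes 2 and 1 (0.175), and of 24 proteasome genes 2 and 3 (0.776), where Psme1, a subunit of the immunoproteasome activator, rose by 0.94 ± 0.15. For proliferation 1 of 14 rose (0.0835). For cholesterol synthesis 0 of 14 were called by limma (0.228; 0 at an unadjusted p under 0.05). For ensheathing glia 3 rose and 4 fell of 9 (0.776), and for endothelial and mural cells 2 rose and 1 fell of 12 (0.313), with the tight junction protein Cldn5 2-fold higher (0.00036). Among lists too short for camera, ependyma and choroid plexus had 2 of 3 higher, among them the ciliary regulator Foxj1 (1.16 ± 0.18). Oligodendrocyte precursors had 1 higher and 2 lower of 3, olfactory sensory neurons 1 and 1 of 4, and red blood cells 0 of 4 called by limma (0 at an unadjusted p under 0.05).

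In all, 691 probe sets were higher and 1443 lower in transgenic bulb at 4 months (limma; 2987 at an unadjusted p under 0.05), and 284 and 81 of them changed more than 2-fold. The balance depended on the scaling: 811 and 960 by quantiles, 789 and 1085 at the 75th percentile, 833 and 932 with values as deposited, and 1120 and 269 with bacterial control scaling, which moved the median of all genes from -0.16 to 0.12.

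**Figure D2:**
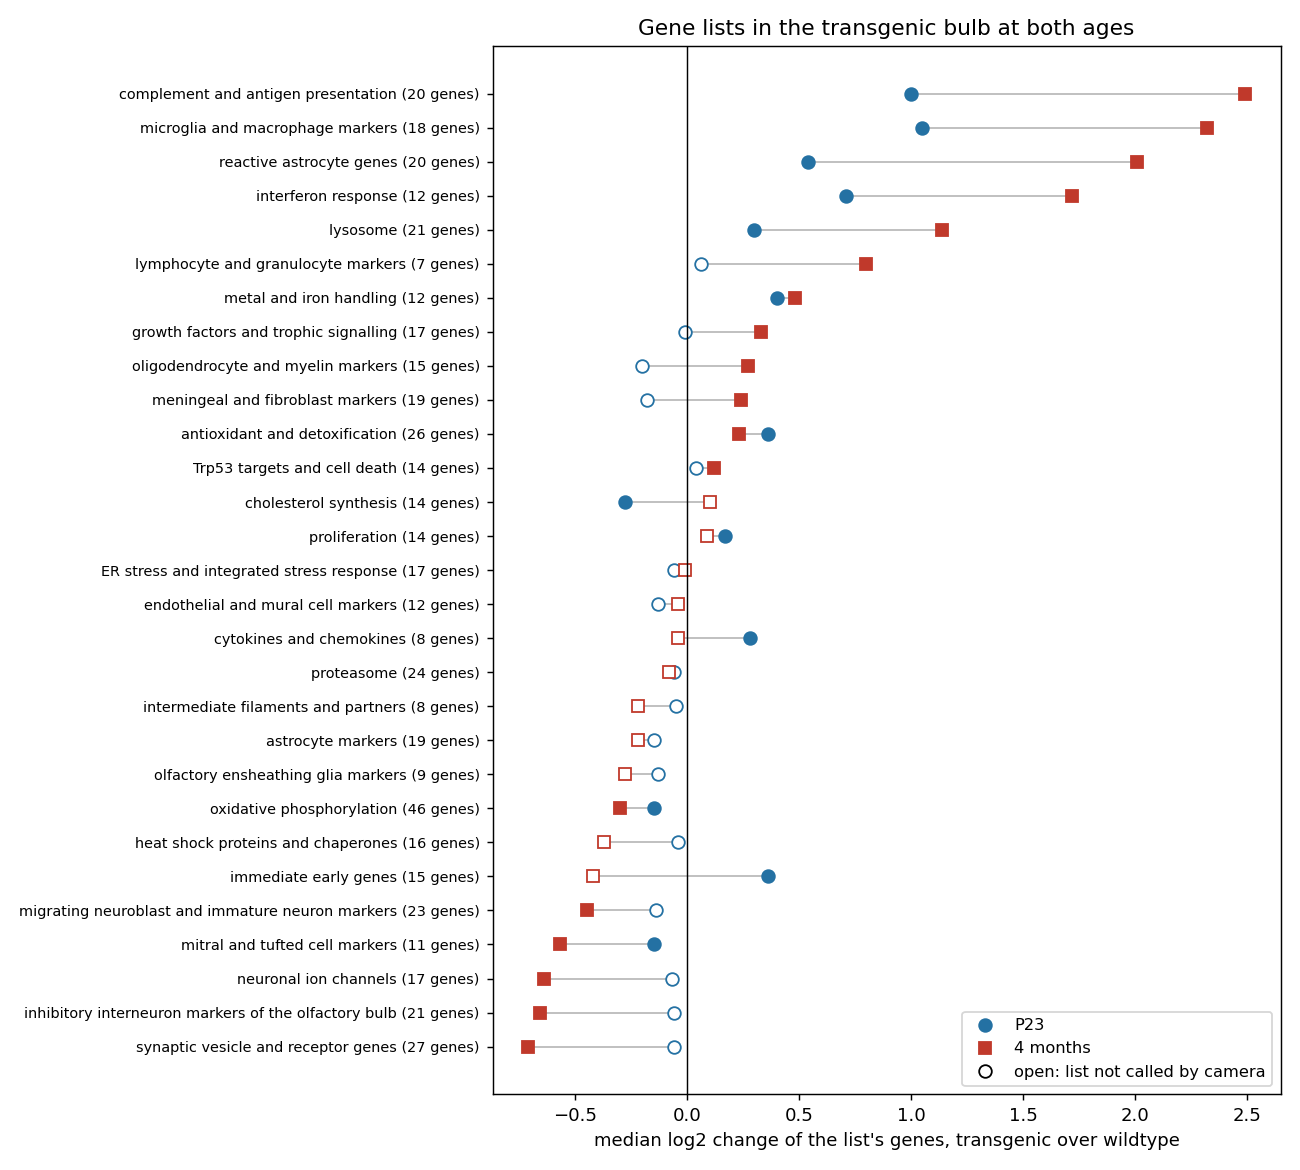
Median log2 change, transgenic against wildtype, of the 29 tested gene lists at P23 (blue circles) and 4 months (red squares), with 3 arrays per group; open symbols are lists not called by camera. Microglia and macrophage markers lie at 1.05 and 2.32, and synaptic genes, not called at P23, at -0.71 at 4 months.

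The calls of the 2 ages, which compare different arrays but share 1 estimate of the spread of each probe set, overlapped. Of the probe sets higher at P23, 113 were also higher at 4 months, against 11.3 expected from independent calls (Fisher's exact test, p = 1.64e-108), and 24 were lower at both, against 6.8 (2.97e-10). Both counts treat probe sets as independent, which they are not. The expected counts also ignore the shared spread, which favours calling the same steady probe sets at both ages. With only the groups compared in each fit, the overlap was smaller. Ccl2, Cxcl1, Ephx1, H2-Aa, Anxa3, Cp, Lyz2 and Igfbp3 were among those higher at both ages and Ntsr2 among those lower at both. For the 122 probe sets higher at P23, the median change was 0.92 at P23 and 1.77 at 4 months. By the estimates alone, 99 of them were further from wildtype at the later age. The interaction test called 54 of the 122 larger and 4 smaller at 4 months. For the 35 lower at P23 the medians were -0.50 and -0.44, and 18 of them were more negative at 4 months. Across all kept probe sets, changes at both ages had a Pearson correlation of 0.467 and a Spearman correlation of 0.22, across genes that are not independent replicates.

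**Figure D3:**
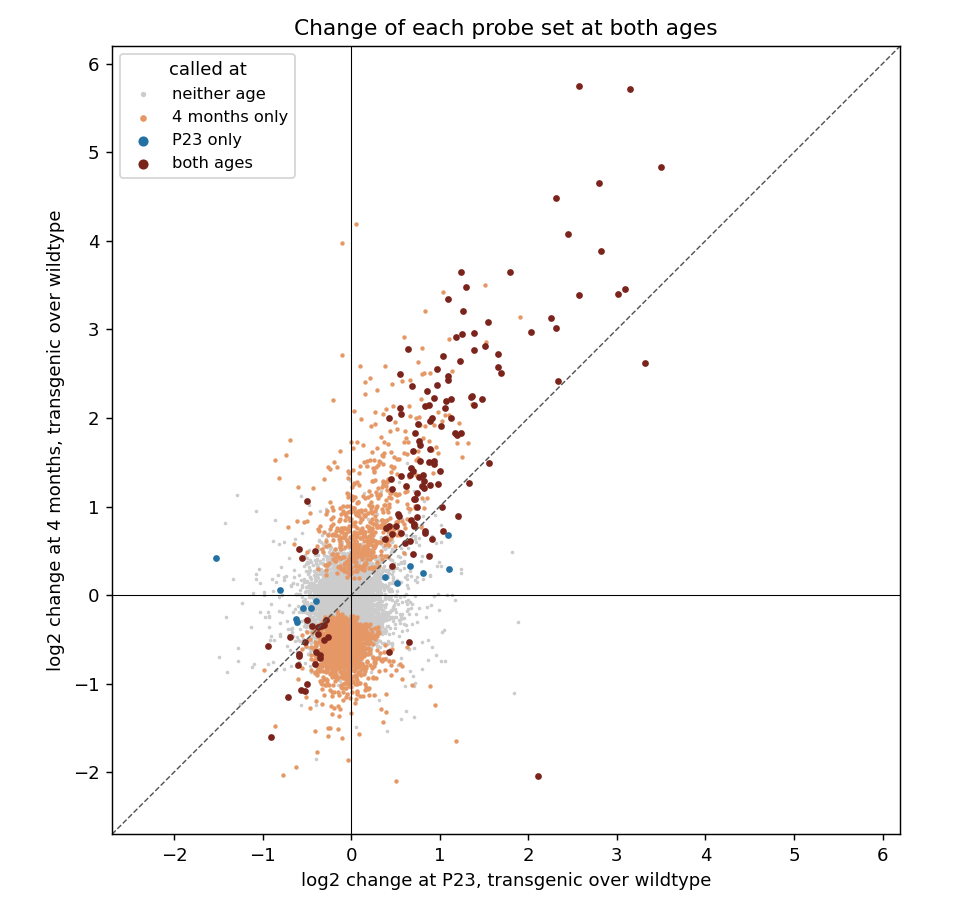
Log2 change, transgenic against wildtype, of 7453 probe sets at P23 (horizontal) and 4 months (vertical), 1 point per probe set, colored by call, with a dashed line of equal change. There were 144 probe sets called at both ages, 1990 at 4 months only and 13 at P23 only.

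The interaction asked whether the genotype difference itself differed between ages. Gfap changed by 1.68 ± 0.21 more at 4 months than at P23 (log2, SE, n = 3 arrays per group; adjusted p = 0.000209), and its second probe set by 1.02 ± 0.27 (0.0309). Postn had the largest increase (4.14 ± 0.26, adjusted p = 8.75e-07), from a change of 0.05 at P23 to 4.19 at 4 months. Mmp12 went from -0.11 to 3.97 and Col5a2, a fibrillar collagen, from -0.10 to 2.71 (2.81 ± 0.22, 3.73e-06). Mpeg1, a pore-forming protein of macrophages, went from 0.10 to 2.58. In the other direction the activity-dependent transcription factors Nr4a1 (-2.60 ± 0.40, 0.00124) and Egr1 (-1.80 ± 0.29, 0.00182) went from 0.50 to -2.10 and from 0.36 to -1.44.

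Complement and antigen presentation genes differed upward in 13 of 20 cases (median 1.62, camera adjusted p = 2.48e-26), microglia and macrophage markers in 13 of 18 (1.29, 4.37e-23), lysosome genes in 15 of 21 (0.91, 3.71e-21) and reactive astrocyte genes in 11 of 20 (1.11, 1.93e-16). Synaptic genes differed downward in 9 of 27 cases (-0.63, 7.56e-10), interneuron markers in 9 of 21 (-0.60, 7.72e-06), ion channel genes in 6 of 17 (-0.62, 3.84e-05) and neuroblast markers in 8 of 23 (-0.24, 3.72e-05; adjusted p = 0.0508 with an estimated correlation). With bacterial control scaling these counts were 3, 0, 0 and 2, with 0, 1, 1 and 0 differing upward and medians of -0.15, -0.12, -0.14 and 0.24. In all, 263 probe sets had a larger and 281 a smaller value at 4 months (limma; 1734 at an unadjusted p under 0.05). The balance depended on the scaling, with 1450 and 26 under bacterial control scaling, which moved the median of all genes by 0.48. The count of smaller values was 152 without wildtype 4 months replicate 10, 185 without 3, 173 without transgenic P23 replicate 5, 158 without 7, and 449 without wildtype P23 replicate 4.

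Between P23 and 4 months in wildtype bulb, markers of immature neurons and of myelin fell, and hemoglobin genes were lower. Mog, a myelin surface glycoprotein, fell from 2680 ± 208 to 1054 ± 62.8 (SD, n = 3; log2 change -1.34 ± 0.15, SE, adjusted p = 0.000712). Cd24a, a surface protein of immature neurons, fell from 10150 ± 1450 to 5464 ± 533 (-0.89 ± 0.12, 0.00404). Neuroblast markers fell in 6 of 23 cases (14 adjusted over the list alone; camera adjusted p = 2.32e-15) and oligodendrocyte and myelin markers in 7 of 15 (1 higher and 8 lower adjusted over the list alone; 2.8e-07). Red blood cell genes fell in 2 of 4 cases (3 adjusted over the list alone; median -1.33, too few for camera), the hemoglobin chains Hba-a1 (-1.29 ± 0.21, 0.0127) and Hbb-b2 (-1.63 ± 0.28, 0.0142). The Hba-a1 call ended without wildtype P23 replicate 12 (0.0773) or wildtype 4 months replicate 9 (0.0645), and the Hbb-b2 call without wildtype P23 replicate 11 (0.0591) or 12 (0.0867) or wildtype 4 months replicate 3 (0.0581) or 9 (0.0699). Of 3 oligodendrocyte precursor markers 0 were called by limma, with 3 lower when adjusted over the list alone and at an unadjusted p under 0.05 (median -0.35). Synaptic genes were shifted upward with 1 of 27 called (8 adjusted over the list alone; 9.67e-05), and ion channel genes with 0 of 17 called by limma (2 adjusted over the list alone, 6 at an unadjusted p under 0.05; 2.86e-05). The lists of interneurons (0.00889; adjusted p = 0.318 with an estimated correlation), immediate early genes (0.00889; adjusted p = 0.337 with an estimated correlation), cholesterol synthesis (0.0207; adjusted p = 0.332 with an estimated correlation) and interferon response (0.0393; adjusted p = 0.337 with an estimated correlation) were called with the preset correlation alone. The immediate early call also ended without wildtype 4 months replicate 3 (0.0991), and the cholesterol synthesis call without wildtype P23 replicate 4 (0.181) or wildtype 4 months replicate 9 (0.0709), with no filter (0.0799) or with a filter at the 60th percentile (0.0646). The interferon response call also ended without wildtype P23 replicate 4 (0.0654) or 11 (0.0737) or wildtype 4 months replicate 3 (0.248), and with no filter (0.326), a floor at the 40th percentile (0.321), array weights (0.0863) or only the groups compared (0.0916).

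In all, 29 probe sets were higher and 47 lower at 4 months in wildtype (limma; 956 at an unadjusted p under 0.05), and 3 and 9 of them changed more than 2-fold. These counts rested on single arrays. The count of higher probe sets was 0 without wildtype P23 replicate 12, 13 without 11 and 56 without 4, 3 without wildtype 4 months replicate 3, 9 without 9 and 2 without 10, 16 without transgenic P23 replicate 5, 15 without 7, and 18 and 15 without transgenic 4 months replicates 1 and 2. The count of lower ones was 6 without wildtype P23 replicate 12, 21 without 11, 26, 13 and 16 without wildtype 4 months replicates 3, 9 and 10, and 30 without transgenic P23 replicate 7.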

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

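The tests chosen only after the result was seen were the spread of the microglia and macrophage markers, the count of lymphocyte and granulocyte markers above the filter, the share of neuronal genes that stay lower under other scalings, and all values with bacterial control scaling or as deposited.

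The genotype difference was tested for a change between ages, and 263 probe sets had a larger and 281 a smaller value at 4 months. In 6 of 100 relabellings of genotype within age, the real one included, at least as many probe sets were called as the real 544, and the highest was 1702. By that test, chance was not excluded for this count. All 6 keep the genotypes of the 4-month arrays, and a split that calls several times the real count points to a structure of the samples, here the genotype difference at 4 months. For lists, 17 of 100 relabellings called at least as many as the real 14, and the highest called 20. Of the 17, 9 keep the genotypes of the 4-month arrays and the others mix them. The mixed ones divide the genotypes unevenly, so that part of the genotype difference at 4 months stays in them. Chance was not excluded for the count of lists, and these relabellings cannot set it apart from that structure.

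Immune lists stood further above wildtype at 4 months than at P23: the median difference was 1.62 for complement and antigen presentation, 1.29 for microglia and macrophages and 0.93 for interferon response. Blood in the transgenic samples was argued against by the red blood cell genes, whose median change at 4 months was -0.06 (4 genes, -0.19 to 0.32; Hba-a1 64960 ± 1710 against 62450 ± 7400 in wildtype). Lymphocytes or granulocytes stay open: with no filter 5.3 percent (1 of 19) of their markers were called higher, but 12 of these lie below the filter, near the floor, where the bound set in advance decides nothing, and 3 of the 7 kept markers, Ighm, Camp and S100a8, rose (median 0.80), where the Camp call ended without wildtype 4 months replicate 10 (0.0644) or transgenic 4 months replicate 8 (0.0583) and the S100a8 call without any of 8 arrays (highest 0.171, without wildtype 4 months replicate 10). More of the resident microglia with unchanged expression was tested by the spread of their 18 kept markers, 5 of which are also on another list. Their changes ranged from 0.33 to 4.48, with an SD beyond measurement error of 0.96. For the 8 markers brighter in wildtype than the median kept value it was 0.98. The test presumes equal changes of all markers, which background signal or expression in other cells would break. It therefore does not decide. A larger number of microglia or macrophages, with or without altered expression, may remain, and a rise within each cell and a change with genotype and age were not tested apart.

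Neuronal lists were further below wildtype at 4 months: the median difference was -0.63 for synaptic genes, -0.62 for ion channels, -0.60 for interneurons, -0.47 for mitral and tufted cells and -0.24 for neuroblasts; with bacterial control scaling, which moves the median of all genes by 0.48, these were -0.15, -0.14, -0.12, 0.01 and 0.24 in the same order. Even dilution of all bulb cells by added cells was argued against by oligodendrocyte and myelin markers. Their median at 4 months lay 0.93 above that of the neuronal genes (bootstrap 95 percent interval 0.62 to 1.42). That interval resamples genes as if independent and does not measure the spread between arrays. The marker list is no fixed reference, since at an unadjusted p under 0.05 (limma) 7 of its 15 genes were higher and 3 lower. A set of 7 structural myelin genes, chosen after the result was seen, had a median of 0.12. Scaling could account for part of the calls: of 66 neuronal genes called lower, 84.8 to 87.9 percent stayed lower under the 3 scalings by percentile, quantiles or deposited values, but 53 percent with bacterial control scaling. That share lies between the bounds set for it, so whether the genes that lost their call are lower stays open. Relative to the median of all genes the neuronal median was -0.50, a distance that a factor per array leaves as it is by construction. By quantiles that distance was -0.46. The difference between ages also holds the age change of wildtype bulb. There 10 synaptic, 6 ion channel and 6 interneuron genes rose and 0 fell (limma, unadjusted p under 0.05). Of mitral and tufted cell markers 1 rose and 1 fell, and of neuroblast markers 0 rose and 14 fell. The age change within transgenic bulb was not tested. Loss of neurons, fewer new neurons and lower expression per neuron stay open and untested.

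The other lists that differed between ages had medians of 0.91 for lysosome genes, 1.11 for reactive astrocyte genes, 0.33 for growth factors (adjusted p = 0.0613 with bacterial control scaling), 0.23 for cholesterol synthesis (adjusted p = 0.195 with an estimated correlation), 0.46 for oligodendrocytes and myelin and 0.41 for meningeal cells and fibroblasts. The mitral and tufted list (adjusted p = 0.195 with an estimated correlation) lost its call without wildtype P23 replicate 4 (0.0624), transgenic P23 replicate 6 (0.0875), wildtype 4 months replicate 3 (0.0618) or transgenic 4 months replicate 1 (0.0755).

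Among single genes the difference between ages was larger at 4 months for Postn (4.14), Mmp12 (4.08), Col5a2 (2.81), H2-Aa (2.57, with wildtype at the floor at both ages), Mpeg1 (2.48), Col3a1 (2.43), Capn1 (2.42), Cd74 (2.40), H2-M3 (2.38) and Pqlc3 (2.31). It was smaller for Gtf2f2 (-2.94), Nr4a1 (-2.60), C2cd2 (-2.19), Rab3a (-1.91), Egr1 (-1.80), Isoc1 (-1.39), Amy1 (-1.38), B3galnt2 (-1.35), Ccdc88a (-1.33) and Egr2 (-1.33). The Gtf2f2 call ended without transgenic P23 replicate 7 (adjusted p = 0.0568) or wildtype 4 months replicate 10 (0.0528), and the Egr2 call without wildtype 4 months replicate 3 (0.0507). The calls of B3galnt2 and Ccdc88a ended without any of 4 arrays, with the highest adjusted p 0.0688 without transgenic 4 months replicate 8 and 0.0798 without transgenic P23 replicate 7. The calls of Rab3a, C2cd2 and Capn1 ended without any of 7, 8 and 9 arrays, with the highest adjusted p 0.0762 without transgenic 4 months replicate 8, 0.0943 without wildtype P23 replicate 12 and 0.102 without wildtype 4 months replicate 10. With no filter the calls of Isoc1 (0.0579), Pqlc3 (0.0678), Egr2 (0.0824), Gtf2f2 (0.109), Ccdc88a (0.123), C2cd2 (0.144), Rab3a (0.146) and Capn1 (0.148) ended, and with a floor at the 40th percentile that of Capn1 (1.17, 0.101). With bacterial control scaling the calls of B3galnt2 (-0.87, 0.119), Ccdc88a (-0.85, 0.0632) and Egr2 (-0.85, 0.0863) ended.

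There were 7 probe sets called in opposite directions at the 2 ages. They were Bgn (-0.59 at P23, a call that ended without any of 4 arrays with the highest adjusted p 0.0835 without transgenic P23 replicate 6, and 0.52 at 4 months; -0.03 and -0.29, not passing, in its other probe set), the second probe set of Aqp4 (-0.40 and 0.50), Sgip1 (0.65 and -0.53), the dimmer probe set of Rpl19 (2.11 and -2.04; -0.05 and 0.20, not passing, in the brighter one), a probe set of Tmem119 and Igfbp5 (-0.50 and 1.07), a probe set of Sgip1 and Noct (0.42 and -0.64) and a probe set without a symbol (-0.56 and 0.42).

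Control probe sets, which the comparisons leave out, also differed at 4 months. The control for mouse Fas was higher by 1.84 ± 0.24 (814.1 ± 40.1 against 229.2 ± 34.7 in wildtype, n = 3; adjusted p = 0.00106), and 1.78 to 2.03 under the other scalings, against a wildtype level close to the floor of 209.142, so that the size of the difference depends on the floor. The beta-actin controls were higher by 0.31 (5' end, adjusted p = 0.0241) and 0.30 (middle, 0.0309), and by 0.37 to 0.59 and 0.37 to 0.58 under the other scalings. The 3' beta-actin control did not pass (0.16, 0.255). Among the bacterial controls, BioC-3 (-0.30, 0.0409), BioC-5 (-0.27, 0.0332) and BioDn-3 (-0.35, 0.0287) were lower by the main scaling. The Gapdh controls were lower by the main scaling (-0.25, -0.31 and -0.26 for the 3', 5' and middle probe sets), but 0.03, -0.03 and 0.02 with bacterial control scaling.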

How the results depend on the processing

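The scalings to bacterial controls and values as deposited were chosen only after the data were seen; the other alternatives were planned. No gene or list result turned its direction past the threshold. For lists this direction is camera's, relative to all other genes, which a factor per array can hardly turn. List medians did change sign, as for neuroblasts in the interaction, and the balance of counts turned with bacterial control scaling. Genes and lists were counted once for each comparison they are reported in. Of 5130 values of the 218 called gene results under alternatives, 4575 kept their call and 555 lost it. Of 1304 values of the 53 called list results, 1237 kept it and 67 lost it. Under every alternative that tested them, the call was kept by 25 of 52 named genes at P23 and 91 of 126 at 4 months. For the interaction these were 11 of 20 and for age 2 of 20. A gene or list that an alternative dropped was not counted as lost. The filter at the 60th percentile tested 67 of 87 genes reported at P23 and 93 of 133 at 4 months. It tested 10 of 20 for the interaction, 14 of 20 for age and 25 of 29 lists. The fit of only the groups compared did not cover the interaction. On the same terms lists kept their call in 7 of 13 cases at P23, 13 of 18 at 4 months, 10 of 14 for the interaction and 4 of 8 for age. Of the values of 63 list results and 42 gene results without a call, counted in the same way, 64 and 27 gained one. Among 7453 probe sets, those near the floor limit what a fold change can show.

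The counts that moved by more than 1.5 times were as follows, and the cause was not tested. Probe sets lower at P23 (35) were 15 by quantiles, 13 without a trend, 60 with array weights, 16 with only the groups compared, 20 with deposited values and 482 with bacterial control scaling. Probe sets lower at 4 months (1443) were 960 by quantiles, 932 with deposited values and 269 with bacterial control scaling, where 1120 were higher (691). For the interaction, smaller values (281) were 185 without a trend, 459 with array weights and 26 with bacterial control scaling, where 1450 were larger (263). For age, higher probe sets (29) were 8 with no filter, 3 without a trend, 76 with array weights, 1 with only the groups compared and 4 with bacterial control scaling. Lower ones (47) were 16, 18, 77, 10 and 78 in the same order. The overlap of both ages (137) was 87 with only the groups compared. With an estimated correlation 8 lists were called at P23 (13) and 4 for age (8).

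Leaving out 1 array gave 12 (transgenic P23 replicate 5) to 38 probe sets lower at P23, 152 (wildtype 4 months replicate 10) to 449 (wildtype P23 replicate 4) smaller values for the interaction, 0 (wildtype P23 replicate 12) to 56 (wildtype P23 replicate 4) higher and 6 to 64 lower for age (the same arrays), and an overlap of 85 (transgenic P23 replicate 5) to 132. The other counts stayed within 1.5 times: 88 to 132 higher at P23, 578 to 717 higher and 966 to 1527 lower at 4 months, and 194 to 295 larger for the interaction.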

Other observations

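The gene families and the comparison of more lower than higher probe sets across scalings were chosen only after the results were seen.

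Several protein families held more higher genes in transgenic bulb at 4 months than all genes would give, with medians above 0 under each scaling tried; some of these genes are also members of the lists fixed in advance. Of 11 cathepsins, lysosomal proteases, 8 were higher (median 1.38, Fisher's exact test, adjusted p = 6.49e-05), among them Ctsc, and 7 of the 8 were on a fixed list. Of 7 annexins, calcium-dependent membrane binding proteins, 6 were higher (1.18, 0.000181), among them Anxa1 and Anxa4, and 2 were on a fixed list. Integrins, a family of adhesion receptors, were higher in 6 of 9 cases (0.72, 0.000917), with Itgax and Itgb7 among them. The same held for tetraspanins in 7 of 14 cases with 2 lower (0.44, 0.00201) and S100 proteins in 5 of 9 (0.35, 0.00889). It also held for serpins in 5 of 10 with 1 lower (0.39, 0.0123) and collagens in 7 of 21 (0.24, 0.0208). Of these higher members, 0 integrins, 3 tetraspanins, 3 S100 proteins, 2 serpins and 1 collagen were on a fixed list. Cathepsins and annexins were higher at P23 as well, in 4 of 11 (adjusted p = 0.000584) and 2 of 7 cases (0.0377).

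In the other direction, 8 of 13 subunits of the vacuolar proton pump, which acidifies synaptic vesicles and lysosomes, were lower and 1 higher at 4 months (median -0.35, adjusted p = 0.011), and 6 of 10 glutamate receptor genes, among them Gria1, Gria2 and Gria3 (-0.69, 0.0377). With bacterial control scaling 0 of the pump subunits were lower (median -0.07) and 4 of the receptors (-0.42). A fixed list held 1 of the 8 lower pump subunits and 3 of the 6 lower receptors. Cytosolic ribosomal proteins were higher in 5 of 23 cases and did not pass (adjusted p = 0.298); the count was 11 by quantiles, 10 at the 75th percentile, 12 with values as deposited and 15 with bacterial control scaling, where the family was not tested. The p-values were adjusted over 72 tests of 18 families. That adjustment does not cover the choice of families after the values were seen, and the test treats genes as independent.

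Cd44, an adhesion receptor, fell below the filter and was not tested; the signal of the brightest of its 3 probe sets was 229.7 ± 35.6 (SD, n = 3) in wildtype and 473 ± 41.2 in transgenic bulb at P23, and 209.1 and 1858 ± 85.9 at 4 months, where all 3 wildtype arrays lay at the floor. Of the other probe sets of Cd44, both lay at the floor on all arrays of 4 months and on the transgenic arrays of P23, and show no rise.

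More probe sets were lower than higher in transgenic bulb at 4 months, 1443 against 691. The scaling may account for this excess, since with bacterial control scaling 269 were lower and 1120 higher. The bacterial controls themselves had a mean log2 signal of 14.11 ± 0.06 in wildtype and 13.84 ± 0.08 in transgenic bulb at 4 months. At P23 they ran the other way, with 13.97 ± 0.08 in wildtype and 14.17 ± 0.13 in transgenic bulb. These controls are added to the labelled sample, so they cannot show how much messenger RNA the tissue held. Whether the transgenic samples received less of the control mixture at 4 months was not tested.

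For these results other splits of the arrays gave fewer calls than the real ones. Splits of 3 against 3 arrays number 10, too few for a share under 0.05: the real split called 157 probe sets at P23 (highest other 0), 2134 at 4 months (highest other 1) and 76 for age (highest other 1), and in each case 1 split, the real one, gave as many. For lists, the real splits called 13 at P23 (highest other 10), 18 at 4 months (highest other 17) and 8 for age (highest other 6), again 1 split each. The other splits called lists too, with a median of 5 at P23, 13 at 4 months (lowest 11) and 2 for age. At 4 months the count of lists therefore sets the real split apart by little. Each other split still has 2 arrays of a real group on 1 side, so part of the real difference stays in it. The lists called there are therefore no measure of chance alone. The 137 probe sets called in the same direction at both ages were reached by 1 of 100 relabellings, the real one, with 7 in the highest other. Since other splits of either age call 0 or 1 probe sets, this share rests on the call counts and does not test the overlap apart from them.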
